A study of Arabidopsis thaliana with 3 samples.

How the data were processed

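RNA-seq of polyA RNA was done in 2 libraries and GMUCT in 1 library, all from immature inflorescences of dcl1-7 plants. Each library came with a table of gene identifiers and RPKM values, deposited by the authors with 2 decimals and no header. Per the submitters' processing notes, adapters were trimmed with cutadapt 1.4.2, reads were aligned with STAR 2.4.0, and the genome build was TAIR10. The counting tool, the annotation release, the read total and gene lengths behind the RPKM values, and the handling of strand and of reads with several matches are not given in the sources used here. The names of the tables say that runs were combined.

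No read counts were used, so depth was estimated from the RPKM values. The RPKM of a low gene times its length falls on steps of 1 read, which gave about 18300000, 8640000 and 19400000 reads for RNA-seq 1, RNA-seq 2 and GMUCT. The rule of taking the largest step that scored close to the best was set after a first search had picked a smaller step for GMUCT. Of the low values 37.6%, 38.0% and 39.0% lay within 0.1 of a whole read, where chance gives 20%. The lengths came from the TAIR10.1 annotation, which need not be the one the authors used. The share of near-whole values was far from complete, so these depths are approximate and no counting intervals were made from them.

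The tables listed 26810 genes in any library and 22417 in all 3. A gene missing from a table was treated as 0 RPKM, and 4 genes were listed at 0 in RNA-seq 1. Chloroplast and mitochondrial genes were not analysed here. Gene symbols, products, exon numbers, GC content and transcript lengths came from the TAIR10.1 annotation, which held 26459 of the identifiers. The build differs in name from that of the authors, so no coordinates are printed. Exon sequences were searched against the TAIR10.1 genome with BLAST 2.17.0, and a gene with at least 95% identity to another place over at least 50% of its exon length was taken to have a near-identical copy. Values of such genes are uncertain because the authors' counting could split or drop their reads.

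Values were compared as log2(RPKM + 0.5), a scale that understates the ratios of low genes. Genes entered where the mean of the RNA-seq mean and the GMUCT value was at least 1 RPKM, which left 20214. The test was limma 3.58.1 (R 4.3.3; lmFit, eBayes with trend), two-sided, with Benjamini-Hochberg adjustment at 0.05. It had 1 residual degree of freedom, and the spread of the lone GMUCT library was assumed to equal that of the RNA-seq libraries. A size rule that needs no such assumption counted genes at least 2-fold from both RNA-seq libraries in the same direction. Count-based tests had been the first choice and were not run because the values are RPKM.

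A total of 14 gene lists were fixed before the data were examined, and 13 had tested members. Each list's median log2 ratio was placed among 10000 random lists of the same size matched on mean RNA-seq level. A list was called outside below percentile 2.5 or above 97.5, as a description of these libraries. Of the 13 lists 6 were outside. The named genes were also fixed by rule: the 12 highest and 12 lowest ratios among called genes with at least 5 RPKM in the higher assay and a value above 0 in every library, the 10 highest values in each assay, the 2 highest and 2 lowest ratios of each list, and DCL1.

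The procedure was tested on simulated data for the GMUCT and RNA-seq comparison over 20214 genes. The simulated GMUCT library was given the same spread beyond counting noise as the RNA-seq libraries. False calls from a GMUCT library that varies more were therefore not tested. With 200 changed genes limma made 0 calls, although the median estimates were 0.93 and 1.92 for true log2 changes of 1 and 2. With 10000 changed genes, a setting added after that outcome, limma recovered 81.3% and 94.9% of the genes at each size, and 59 of its 8868 calls were false. The number of limma calls therefore depends on many genes differing, and the size rule does not. Of 100 random lists drawn from all simulated genes, changed ones included, 5 and 2 were outside in the simulations. Alternatives covered centring, filters, pseudocounts, trends with length, limma without trend, fold thresholds, matching of random lists and leaving out each RNA-seq library. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.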

Results

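Immature inflorescences of Arabidopsis thaliana were profiled in dcl1-7, a mutant of DCL1, the Dicer enzyme that cuts microRNA precursors. Buds came from plants of about 4 weeks grown in 16 h of light and 8 h of dark, and polyA RNA was sequenced in strand-specific reads of 50 nt. RNA-seq was done in 2 libraries and GMUCT in 1. GMUCT sequences the 5′ ends of polyA RNAs that carry no cap, so its reads come from decapped or cut transcripts. All GMUCT values below are therefore single measurements without a replicate error. RNA-seq values are given as mean ± SD over 2 libraries, in RPKM, a read number scaled to gene length and library size. Depth was estimated from the spacing of low values at about 18300000 and 8640000 reads for RNA-seq libraries 1 and 2, and at about 19400000 for GMUCT. The libraries listed 23809, 22824 and 26731 genes. A value of at least 1 RPKM was reached by 18684, 18628 and 20991 of them.

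The mutated gene itself, DCL1 (AT1G01040), was listed at 16.04 and 15.18 RPKM in the RNA-seq libraries, a mean of 15.6 ± 0.608 RPKM. Its GMUCT value was 7.57 RPKM, a log2 ratio of -0.997 (SE 0.08; limma adjusted p = 0.0082). The ratio was -0.04 and no longer past the test once a trend with gene length was removed. Libraries of another genotype were not analysed here, so these values do not check the genotype label.

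The 2 RNA-seq libraries were close to each other across the 20214 tested genes. Pearson's r was 0.993 and Spearman's rho was 0.994 on the log2(RPKM + 0.5) scale, across genes, which are not independent replicates. The SD of their log2 ratio was 0.22, and 67 genes (0.331%) were 2-fold or more apart.

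The comparison within the genotype asks which transcripts have more or fewer uncapped ends than their abundance in polyA RNA. GMUCT followed RNA-seq much less closely than the RNA-seq libraries followed each other. Across genes, r between GMUCT and the RNA-seq mean was 0.717 and rho was 0.723. The log2 ratio of GMUCT to RNA-seq had a median of -0.07 and an SD of 1.36. GMUCT lay at least 2-fold above both RNA-seq libraries for 4021 genes and at least 2-fold below both for 3496, while 12697 genes met neither rule. At a mean of at least 5 RPKM the balance turned, with 2499 genes above and 2740 below. The 4-fold rule was met by 1760 genes on the high side and 395 on the low side. The 1760 genes had low mRNA levels, with a median of 0.51 RPKM in RNA-seq and 12.1 RPKM in GMUCT, and 1008 of them were below 1 RPKM in RNA-seq. The 395 genes on the low side were abundant mRNAs, with medians of 27.4 RPKM in RNA-seq and 5.01 RPKM in GMUCT.

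By limma with Benjamini-Hochberg adjustment, 6489 genes were higher and 7468 lower in GMUCT, 69.0% of those tested. Without the filter on low values the balance turned, with 9098 higher and 6325 lower. The test had 1 residual degree of freedom and assumed that the lone GMUCT library varies like the RNA-seq libraries. Nothing in the labels says that the RNA-seq libraries came from separate plants, so p-values measure only the spread between these samples, which may be technical.

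**Figure D1:**
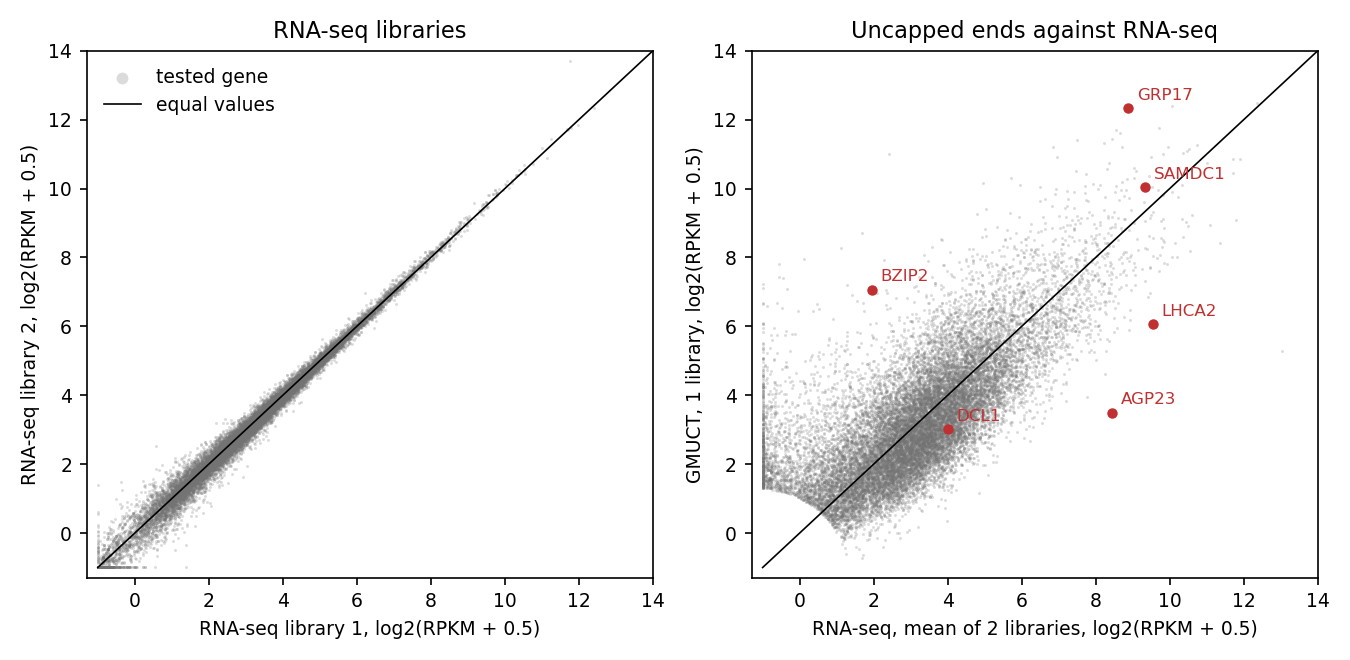
Each point is 1 of 20214 tested genes on log2(RPKM + 0.5) axes, RNA-seq library 1 against library 2 on the left and the RNA-seq mean against the single GMUCT library on the right, with the line of equal values. The RNA-seq libraries lie along the line (r = 0.993), while GMUCT scatters widely around it (r = 0.717), with BZIP2 and GRP17 above it and AGP23 and LHCA2 below it.

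Among called genes above 0 in all 3 libraries and with at least 5 RPKM in GMUCT, the 12 with the highest GMUCT to RNA-seq ratios all had less than 5 RPKM in RNA-seq. AT2G07751 ranked first on the log2(RPKM + 0.5) scale, which understates the ratios of genes with less mRNA, with 4.87 ± 3.19 RPKM in RNA-seq and 2044 RPKM in GMUCT (log2 ratio 8.71). It encodes a protein of the NADH dehydrogenase chain 3 family, and 100% of its exon length matched the mitochondrial genome, so its reads cannot be assigned to the nuclear copy with certainty. AT1G58120 went from 0.185 ± 0.191 to 173.9 RPKM (log2 ratio 8.02), and AT3G28600, a P-loop nucleoside triphosphate hydrolase, from 0.230 ± 0.0141 to 168.8 RPKM (7.86). The beta-galactosidase gene BGAL14 had 0.295 ± 0.120 RPKM in RNA-seq and 135.2 RPKM in GMUCT (7.42). TTG2, a WRKY transcription factor of trichome and seed coat development, had 0.160 ± 0.156 and 53.3 RPKM (6.37). The RING/U-box gene AT2G25410 had 0.070 RPKM in both RNA-seq libraries and 41.2 RPKM in GMUCT (6.19). AT2G15830, AT5G24250, AT1G35255 and AT1G34315 had log2 ratios of 7.16, 6.53, 6.50 and 6.23. AT5G27247 (7.88) and AT1G24996 (7.02) completed the 12, both uncertain because 98.0% and 100% of their exon length has a near-identical copy elsewhere. Some of these ratios rest on very few RNA-seq reads. The estimates for libraries 1 and 2 were 1.65 and 0.78 reads for AT2G25410 and 1.00 and 1.00 for AT5G27247. In library 2 they were 0.89 for AT1G58120 and 0.80 for TTG2, against 8.05 for AT2G07751.

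The 12 genes with the lowest ratios all had more than 10 RPKM in RNA-seq. AGP23, a pollen arabinogalactan protein, had 348.5 ± 29.1 RPKM in RNA-seq and 10.8 RPKM in GMUCT (log2 ratio -4.95, SE 0.10). LHCA2, an antenna protein of photosystem I, had 749.5 ± 30.6 and 66.5 RPKM (-3.48). The ribosomal protein gene AT3G24830 had 217.4 ± 3.03 and 15.02 RPKM (-3.81), and AT5G22440, another ribosomal protein gene, had 66.4 ± 0.424 and 6.24 RPKM (-3.31). The actin gene ACT8 had 94.0 ± 1.51 and 8.58 RPKM (-3.38). The log2 ratio was -3.67 for PUB12, -3.63 for UNE15, -3.62 for the lipid transfer protein gene AT5G44265 and -3.55 for sks11. It was -3.42 for AT5G06043 and -3.37 for AT2G42310, a subunit of mitochondrial complex I. AT2G01021 had the lowest ratio (-7.46), but this gene of 102 nt is fully copied elsewhere in the genome and differed between the RNA-seq libraries, at 3444 and 13422 RPKM. Its call was lost without the filter on low values.

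VSP1, a vegetative storage protein, was the most abundant GMUCT gene and among the most abundant in RNA-seq, with 5286 ± 170.3 RPKM in RNA-seq and 5758 RPKM in GMUCT, and it did not pass the test. The other most abundant RNA-seq genes included the photosynthesis genes LHCB1.3, called lower in GMUCT, RBCS3B (3842 ± 269.7 against 1846 RPKM, not past the test), LHCB1.5 (3348 ± 94.4 against 1397 RPKM, called lower), RBCS1A (3342 ± 29.8 against 1843 RPKM, not past the test) and LHCA1 (2066 ± 263.2 against 1719 RPKM, not past the test). The metallothionein gene MT2B had 2609 ± 229.9 RPKM in RNA-seq and 342.03 RPKM in GMUCT (log2 ratio -2.93). Another metallothionein gene, MT3, lay on the opposite side, with 834.1 ± 97.4 and 3438 RPKM (2.05). Lipid transfer proteins also went both ways, with LTP1 at 2174 ± 166.4 and 494.2 RPKM (-2.13) and LTP6 at 1072 ± 54.9 and 5357 RPKM (2.32). The ribosomal L29e gene AT3G06700 was higher in GMUCT, with 300.1 ± 9.26 and 2571 RPKM (3.097). AT2G44670 (3.93), AT4G29030 (3.15) and AT4G23680 (2.97) were likewise among the 10 most abundant GMUCT genes. LHCB2.2, in the top 10 of both assays, had 1702 ± 40.4 and 2460 RPKM and did not pass the test. Its values are uncertain, because 65.7% of its exon length has a near-identical copy.

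Genes with a conserved peptide uORF, an upstream reading frame whose peptide controls translation of the main protein, had the highest median of the lists. Of 10 tested genes 7 were higher in GMUCT, 1 was lower and 2 did not pass, with the same counts adjusted over the list alone. The transcription factor genes BZIP2 and BZIP53 had 3.40 ± 0.919 and 1.80 ± 1.24 RPKM in RNA-seq but 133.1 and 38.9 RPKM in GMUCT, log2 ratios of 5.12 and 4.22. CIPK6 was lower, with 173.5 ± 1.88 and 86.3 RPKM (-1.004), and BZIP44 had 50.0 ± 3.77 and 46.7 RPKM without passing the test. The list's median log2 ratio of 1.28 lay at percentile 99.79 of 10000 random lists matched on RNA-seq level. Its percentile was 77.08 when only genes of at least 5 RPKM were used, and the call of BZIP53 was lost without any filter.

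Core histone genes were the other list above its matched random lists, with a median of 0.61 at percentile 99.99. With the length trend removed the median was 0.12, at percentile 99.68. Of 25 genes 14 were higher, 8 lower and 3 not past the test, and counts adjusted over the list alone were the same. The histone genes AT3G46320 and AT3G45930 had 52.0 ± 3.07 and 122.9 ± 2.80 RPKM in RNA-seq and 1274 and 1947 RPKM in GMUCT (log2 ratios 4.60 and 3.98). Both values are uncertain, because 61.0% and 56.5% of their exon length has a near-identical copy. At the low end lay the histone gene AT4G40030, with 355.2 ± 4.30 and 107.1 RPKM (-1.72), and the H2A gene HTA10, with 199.2 ± 12.3 and 61.7 RPKM (-1.68). A further histone gene, AT4G40040, went the other way at 343.7 ± 26.8 and 2789 RPKM (3.02). The excess depended on which histone genes were taken. With random lists also matched on length, the list of 25 lay at percentile 99.69. The 31 tested genes with the product name Histone superfamily protein, compared after the data were seen, had a median of 0.24. They lay at percentile 84.52 under the same matching, and at 75.16 with introns matched as well, inside the random range.

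Genes of the small RNA pathway were mostly lower in GMUCT. Of 28 genes 21 were lower, 3 higher and 4 not past the test, likewise adjusted over the list alone. The Argonaute genes AGO10 and AGO2 had 29.4 ± 1.06 and 25.1 ± 0.834 RPKM in RNA-seq and 8.35 and 7.17 RPKM in GMUCT (log2 ratios -1.76 and -1.74). HYL1 and DDL, partners of DCL1 in microRNA processing, lay on the high side, at 8.71 ± 0.0212 and 11.2 ± 0.537 RPKM against 25.8 and 32.0 RPKM (1.51 and 1.48). The median of the list was -0.97, at percentile 0.11 of the matched random lists. With the length trend removed it was -0.52, at percentile 11.35. When random lists were instead matched on length as well, the list stayed outside at percentile 1.98, so the 2 length controls differed.

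Of 28 RNA decay factors 16 were lower, 9 higher and 3 not past the test, likewise adjusted over the list alone. The nuclear exoribonuclease gene XRN3 had 14.5 ± 0.516 and 2.2 RPKM (-2.47), and VCS, a scaffold of the decapping complex, had 23.4 ± 0.643 and 4.34 RPKM (-2.30). The deadenylase gene CAF1A (3.27 ± 0.785 and 15.2 RPKM, 2.07) and DCP2, the decapping enzyme (7.13 ± 0.276 and 22.8 RPKM, 1.61), were higher in GMUCT. The list's median was -0.74 at percentile 1.95, at percentile 8.22 when random lists were also matched on length, and -0.44 with the length trend removed. Without RNA-seq library 1 it was -0.69, at percentile 3.62.

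Tapetum and pollen wall genes, late pollen genes, and vascular, epidermal and trichome markers were mostly lower in GMUCT. The floral organ identity and photosynthesis lists, also fixed as markers and given further below, lay within the range of their random lists. Of 20 tapetum and pollen wall genes 14 were lower, 3 higher and 3 not past the test, and 15 and 4 passed on each side adjusted over the list alone. Their median was -1.10 at percentile 0.72. The pollen wall gene ACOS5 had 68.5 ± 4.60 and 10.9 RPKM (-2.60), and the lipase gene EXL6 had 156.9 ± 2.56 and 36.2 RPKM (-2.10). The pollen coat gene GRP17 was higher, with 471.6 ± 40.7 and 5176 RPKM (3.46), as was TKPR1, with 86.5 ± 5.30 and 271.2 RPKM (1.64). Of 14 late pollen genes 11 were lower, none higher and 3 not past the test, likewise adjusted over the list alone. RALF4 had 38.7 ± 3.16 and 3.70 RPKM (-3.22) and VGD1 had 246.9 ± 17.9 and 37.7 RPKM (-2.69), while AGP6 (59.4 ± 8.90 and 78.8 RPKM) and AGP11 (40.3 ± 3.66 and 50.7 RPKM) did not pass. Their median of -0.89 was at percentile 3.53, inside the middle 95% of random lists. Of 10 vascular, epidermal and trichome markers 8 were lower and 1 higher, and 8 and 2 adjusted over the list alone, with a median of -1.08 at percentile 1.25. The epidermal LTP1 and the cellulose synthase gene IRX3 (9.46 ± 1.61 and 3.72 RPKM, -1.23) had the lowest ratios of that list. GL2 was higher (1.34 ± 0.247 and 2.75 RPKM), and VND7 had 0.750 ± 0.297 and 2.21 RPKM without passing. The vascular list lay at percentile 7.43 with the length trend removed and 3.03 above 5 RPKM. It lay at percentile 2.37, still outside, when random lists were also matched on length. The IRX3 and GL2 calls were lost without the low-value filter, the IRX3 call also with the length trend removed, and the GL2 call also with a pseudocount of 0.1 or a GC trend removed.

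**Figure D2:**
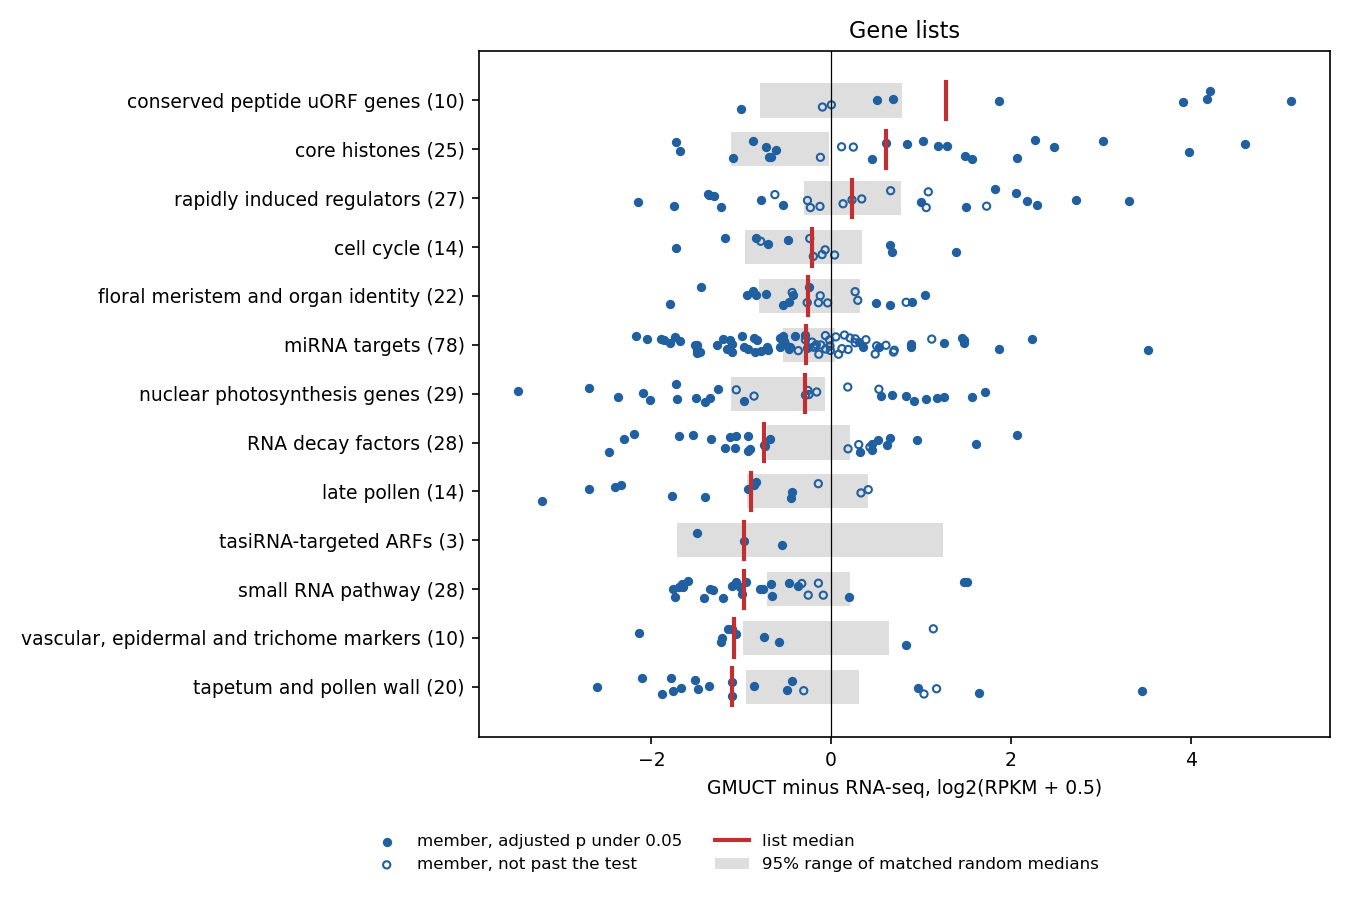
Each row is a gene list with its number of tested genes, and each point is a member's difference between GMUCT and mean RNA-seq on the log2(RPKM + 0.5) scale, filled where the limma adjusted p is under 0.05. Red bars are list medians and grey bars the middle 95% of medians of 10000 random lists matched on RNA-seq level; 6 medians lie outside, from 1.28 for conserved peptide uORF genes to -1.10 for tapetum and pollen wall genes.

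The known targets of microRNAs lay within the range of matched random lists, with a median of -0.28 at percentile 41.82. Of 78 tested targets 37 were lower in GMUCT, 12 higher and 29 not past the test, and 34 and 11 passed adjusted over the list alone. SPL9, a target of miR156, had 44.4 ± 1.48 and 9.49 RPKM (-2.17), and APS3, a sulfurylase gene targeted by miR395, had 13.9 ± 1.03 and 2.98 RPKM (-2.05). GRF4, a target of miR396, was on the high side, with 4.62 ± 0.141 and 23.6 RPKM (2.23). SPL13B had no value in the RNA-seq tables used here and 5.24 RPKM in GMUCT, left uncertain by a copy over 100% of its exon length. The 3 auxin response factor genes targeted by trans-acting siRNAs were all lower, also adjusted over the list alone, with a median of -0.97 at percentile 23.91, or -0.37 at percentile 58.32 with the length trend removed. ARF4 had 19.1 ± 1.15 and 6.43 RPKM (-1.50), ARF2 137.2 ± 5.93 and 69.9 RPKM (-0.97), and ARF3 17.7 ± 1.42 and 11.97 RPKM (-0.54). The ARF3 call was lost with the length or GC trend removed and without the low-value filter.

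The remaining lists also lay within the range of their matched random lists. Of 29 nuclear photosynthesis genes 12 were lower, 9 higher and 8 not past the test (13 and 9 adjusted over the list alone), with a median of -0.29 at percentile 85.31. Members of the same protein family went both ways. LHCB1.3 had 3517 ± 47.8 and 542.6 RPKM (-2.70), although 67.6% of its exon length has a near-identical copy, whereas LHCB1.4 had 36.6 ± 6.87 and 120.02 RPKM (1.71) and RBCS1B 524.2 ± 15.2 and 1552 RPKM (1.57). Of 27 rapidly induced regulators 8 were higher, 8 lower and 11 not past the test, likewise adjusted over the list alone. Their median of 0.23 at percentile 54.05 had no stable sign: it was -0.01 (percentile 30.57) without RNA-seq library 1, 0.48 (percentile 76.86) without library 2, -0.08 with the length trend removed and -0.53 at 5 RPKM. TCH2, a touch-induced calmodulin-like gene, had 27.2 ± 1.44 and 274.9 RPKM (3.31) and CBF1 0.3 ± 0.0990 and 4.75 RPKM (2.72), against IAA1 with 12.04 ± 2.18 and 2.31 RPKM (-2.15) and JAZ10 with 8.47 ± 0.368 and 2.17 RPKM (-1.75). Among 22 floral meristem and organ identity genes 10 were lower, 4 higher and 8 not past the test, likewise adjusted over the list alone (median -0.26, percentile 53.42). AP2 had 29.6 ± 0.785 and 8.18 RPKM (-1.79) and SEP3 138.7 ± 3.47 and 50.5 RPKM (-1.45), while AP3 had 89.3 ± 0.0778 and 166.4 RPKM (0.89) and SHP1 5.47 ± 0.495 and 11.8 RPKM (1.04). Among 14 cell cycle genes 5 were lower, 3 higher and 6 not past the test, likewise adjusted over the list alone (median -0.22, percentile 66.2). The cyclins CYCB1;2 and CYCB1;1 were lower, at 22.1 ± 1.75 and 8.42 ± 0.198 RPKM against 6.34 and 3.44 RPKM. The spindle checkpoint gene MAD2 (10.7 ± 0.686 and 28.8 RPKM, 1.39) and KNOLLE, a syntaxin of cell plate formation (52.7 ± 0.884 and 84.4 RPKM, 0.67), were higher. The LHCB1.4 call was lost without the low-value filter, the LHCB1.5 call without that filter or with a pseudocount of 0.1, and the SHP1 call with a GC trend removed. With the length trend removed the medians were -0.59 for photosynthesis, -0.41 for floral and -0.38 for cell cycle genes. The floral median was -0.42 at 5 RPKM and -0.43 with a GC trend removed, and the microRNA target median was -0.15 without the low-value filter. Precursors of trans-acting siRNAs were not analysed here.

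The ratio was higher for short transcripts and lower for long ones. Median log2 ratios went from 0.76 in the shortest of 10 equal length groups, with a median length of 678.5 nt, to -0.76 in the longest, with a median length of 3710 nt. Spearman's rho between length and the ratio was -0.31 across genes.

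**Figure D3:**
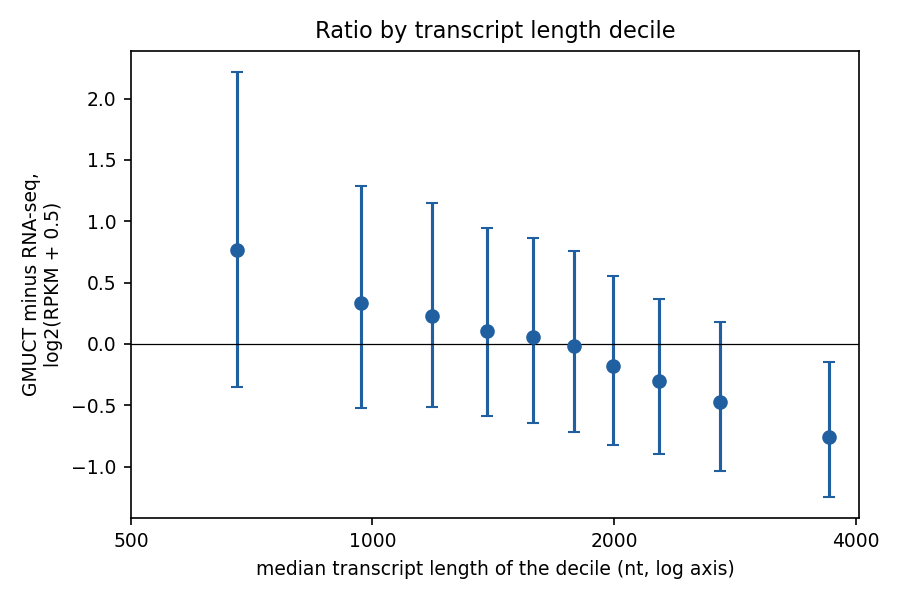
Median log2 ratio of GMUCT to RNA-seq on the log2(RPKM + 0.5) scale for 10 groups of tested genes of increasing transcript length (log axis, nt), with bars from the lower to the upper quartile of genes. The medians go down from 0.76 in the shortest group to -0.76 in the longest.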

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

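Removing a trend with GC content, leaving out genes with near-identical copies, using only genes listed in all 3 tables, and matching random lists on introns were chosen after seeing the data. The planned count-based fits were not run because the values are RPKM, and leaving out organelle genes gave no value because those genes were not analysed here. No paired analysis was possible because the groups share only 1 replicate number. Leaving out an RNA-seq library leaves limma no residual degrees of freedom, so its counts have no such value. None of the called genes among the 89 named and no list outside its random lists changed direction under the alternatives run, but the balance of higher and lower genes did. The 13957 limma calls became 7965 when a 2-fold ratio was also required (4186 higher, 3779 lower), which is narrower by construction. The higher share of calls was 46.5%, 49.7% with median-centred ratios and 59.0% without the filter, which adds low genes and gave 9098 higher and 6325 lower. The 7517 genes of the size rule became 2155 at 4-fold (1760 higher, 395 lower), and its 4021 higher genes became 2499 among the 13638 genes of at least 5 RPKM, where the lower genes, 2740, outnumbered them. Without either RNA-seq library the size rule gave 8141 to 8162 genes, as only 1 library then had to be 2-fold away. The correlation across genes was 0.843 without a filter, 0.588 from 5 RPKM, and 0.713 to 0.719 without either RNA-seq library.

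The core histone and tapetum lists kept their side of the percentile range under every alternative run. With the length trend removed, the small RNA pathway (-0.52), RNA decay (-0.44) and vascular (-0.81) lists were no longer outside, and late pollen (-1.01) was. The small RNA pathway and vascular lists stayed outside when random lists were instead matched on length. RNA decay factors were also inside with the GC trend removed (-0.73), with random lists matched on length (-0.74), and without RNA-seq library 1; without either library their median was -0.69 to -0.79. At 5 RPKM the uORF list (1.28) and the vascular list (-1.13) were inside, and there a gene with little mRNA enters only with high GMUCT. Late pollen genes were outside without a filter (-0.85), with a pseudocount of 0.1 (-0.99) and with lists matched on introns (-0.89). The cause of these moves was not tested beyond the corrections themselves. Of the 89 named genes' values under alternatives, 1013 stayed on the same side of the threshold or within the spread, 20 gained a call, 15 lost it and 4 moved without a test. Depth limits the genes below about 1 RPKM in RNA-seq, whose ratios rest on few estimated reads.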

Other observations

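Gene families that the report did not list were compared after the data were seen, using annotated product names, and some medians had been looked at before the test. Of 157 families with at least 15 tested genes, 5 lay outside random lists matched on length and RNA-seq level after Benjamini-Hochberg adjustment, all on the high side. Glycine-rich proteins had a median log2 ratio of 2.21 over 46 genes, of which 35 were higher and 6 lower in GMUCT by limma. AT1G04800 of that family had 27.2 ± 1.90 RPKM in RNA-seq and 611.2 RPKM in GMUCT. Genes with the product name AGAMOUS-like had a median of 1.82 over 27 genes, 14 higher and 7 lower. AGL65 lay on the high side at 1.32 ± 0.0778 and 36.2 RPKM, and AGL104 on the low side at 4.49 ± 1.05 and 0.92 RPKM. This was not a trait of all MADS-box genes: those named K-box region and MADS-box transcription factors had a median of -0.23 over 15 genes. Of these, 5 were higher and 6 lower, and the median lay at percentile 34.2. Genes of the HSP20-like chaperone superfamily had a median of 1.62 over 28 genes, 18 higher and 2 lower, with RTM2 at 3.37 ± 0.127 and 53.3 RPKM. CBL-interacting protein kinases had a median of 1.16 over 18 genes, 12 higher and 1 lower, with CIPK7 at 44.95 ± 1.60 and 211.6 RPKM. CIPK6, called lower in GMUCT, has another product name and is not among the 18. UDP-glycosyltransferases had a median of 0.67 over 62 genes, 33 higher and 14 lower, with GT72B1 at 45.9 ± 4.74 and 200.6 RPKM and SGT at 11.9 ± 0.396 and 3.19 RPKM. Genes without introns, which had higher ratios in general, made up 27 of the 62 UDP-glycosyltransferases, 10 of the 18 kinases, 15 of the 46 glycine-rich, 7 of the 28 HSP20 and 7 of the 27 AGAMOUS-like genes. With random lists matched on introns as well, the 5 medians lay at percentiles 99.62, 99.75, 100, 99.95 and 99.96 in that order, not adjusted over the families. The members named here were chosen after their values were seen.

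Genes annotated in the nucleus that resemble organelle DNA were compared after the data were seen. Of 54 tested nuclear genes with at least 50% of their exon length matching an organelle genome, 41 were at least 2-fold higher than both RNA-seq libraries and 3 at least 2-fold lower, with a median log2 ratio of 1.78. The 2-fold higher share was 75.9%, against 19.9% of all tested genes. The median lay at percentile 100 of random lists matched on RNA-seq level and 99.99 of lists also matched on length. All but AT3G20362 and AT2G12905 carry identifiers from a narrow range of chromosome 2, so the percentiles do not rest on independent genes. Some members went the other way, among them AT2G07739, a Ycf1 protein gene (log2 ratio -1.65), and AT2G07732, a Rubisco large chain gene (-0.63, not past the test). Since 53 of the 54 match organelle DNA over at least 90% of their exon length, their reads cannot be assigned to the nuclear copies.

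Of the tests that follow, the whole-cause test of the length slope and the test on genes of at least 10 RPKM in both assays were chosen after the results were seen, and the idea of comparing genes by introns came from looking at families. The ratio of GMUCT to RNA-seq fell with transcript length. If each molecule gave 1 GMUCT read while RNA-seq reads grew with length, and nothing else acted, the slope of the log2 ratio on log2 length would be near -1 and at or below -0.75. The observed slope was -0.58 (bootstrap 95% interval -0.61 to -0.55), shallower than that bound. The interval covers neither the effect of the pseudocount nor errors in the lengths. Within these limits the slope argues against this explanation as the whole cause, but the explanation may be part of the cause. Different expression levels of long and short genes stay open in part: within 10 level bins the median slope was -0.51 and all 10 slopes were negative, but the range of -0.67 to -0.19 missed the bound of -0.25 set beforehand in at least 1 bin. No biological explanation was tested, because the design has 1 genotype.

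More genes were at least 4-fold higher than at least 4-fold lower in GMUCT. Among genes with a mean over both assays of at least 10 RPKM 703 were higher and 272 lower, a ratio of 2.58 (exact 95% interval 2.24 to 2.98), although genes with little mRNA can enter there through GMUCT. With at least 10 RPKM in both assays 300 were higher and 109 lower, a ratio of 2.75 (2.203 to 3.46), which argues against counting noise of low values. Reads shared with near-identical copies could account for few of the genes: of the 1677 4-fold higher genes with an annotated sequence to search, 8.53% had a copy (exact 95% interval 7.23 to 9.97), against 1.68% of other tested genes. Reads piled at single cut sites, amplification of single molecules and differences in library preparation stay open, because the tables hold 1 value per gene, and no biological explanation was tested.

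Genes without introns had a higher ratio than genes with introns, with medians of 0.66 over 3120 genes and -0.19 over 16952. A hypothesis was that their length and level explain this. Within 25 strata of length and level, the difference in medians was 0.587 and it was positive in 25 of 25. The difference in means within the strata, on which the permutation test was run, was 0.553 (permutation p = 1e-05, the smallest that 100000 permutations give). After genes with near-identical copies were left out, the difference in medians was 0.606 and that in means 0.569 (permutation p = 1e-05 for the means, likewise the smallest). Reads shared with such copies therefore do not account for the difference. Shorter shared stretches were not examined. The smaller difference within strata than between the plain medians leaves length and level open as part of the cause, but not as the whole. The p-values treat genes as independent, which they are not. Traces of genomic DNA, differences in library preparation and the turnover of intronless transcripts remain untested as candidate explanations.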
